A study of Mus musculus with 24 samples.

How the data were processed

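The series holds 24 samples of NOS1-positive N1E115 cells, a mouse neuroblastoma line, kept for 3 days at 20% or 4% oxygen. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for 5 histone marks, H3K4me3, H3K27ac, H3K4me1, H3K36me3 and H3K27me3, with 2 libraries per mark and oxygen level. The remaining 4 samples were inputs, for which no file was used here. Libraries were assigned to mark, oxygen level and replicate from the sample titles alone. Replicate 1 of every mark is called set 1 and replicate 2 set 2; per the labels, each set had its own input number. Nothing in the labels says whether the libraries of a group came from separate cultures, so the spread between libraries may be technical. Only the exact permutation tests of 2 against 2 libraries and the edgeR and DESeq2 fits have libraries as units. The random-list, Fisher's exact and sign tests count genes, regions or chromosomes, so their p-values do not measure the spread between libraries.

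Reads were aligned with BWA to mm10 and treated with Picard, and peaks called with MACS2 or SICER, per the submitters' processing notes and the file headers; versions were not given in the sources used here. Peaks were called per library, per the file headers. The deposited lists for H3K4me3, H3K27ac and H3K4me1 are MACS2 peaks whose score is a −log10 value, taken here as −log10 q from the layout of the values. The lowest deposited score lay between 2.01 and 2.11 in the 12 lists of these marks. The deposited lists for H3K36me3 and H3K27me3 are SICER islands with an unlabelled last column of whole numbers, read here as ChIP read counts per island. Scores and counts per peak are the authors' own values, and scores served only to rank peaks within a list. Per the file headers the libraries came from 3 flow cells. In set 2 all libraries shared a flow cell. In set 1 the 20% libraries and the 4% H3K4me1 library shared a flow cell, while the other 4% libraries of that set were on another one, so that oxygen and flow cell were confounded there for those marks.

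For the MACS2 marks, the file listed under the second library held peak summits only, and its intervals were in a further file listed under the first library. Peak names and scores of these pairs matched for 100% of entries, and every summit lay inside its interval, so the intervals were assigned to the second library. For the SICER marks the corresponding files matched in 100% of entries and were used once.

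Peaks on chromosomes 1 to 19, X and Y were kept. For each mark, overlapping or touching peaks of the 4 libraries were merged into regions. A region was called 4%-only when both 4% libraries and neither 20% library had a peak in it by at least 1 bp, and 20%-only the other way round. The number of such regions was set beside the 2 other ways of splitting the 4 libraries into pairs, by set and crossed. The presence of a peak was not tested region by region, since the smallest exact permutation p for 2 against 2 libraries is 0.333. Direction was compared between the sets: among regions decided in both, Fisher's exact test (two-sided) of the direction in set 1 against that in set 2 gave an odds ratio with its 95% interval, with Benjamini-Hochberg adjustment over the 5 marks, and an exact sign test over chromosomes.

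Gene positions came from a RefSeq gene table for GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. The table has no strand, so the planned window around the transcription start was replaced by windows around both ends of the gene record. A gene carried a mark where peaks covered at least 200 bp of either end within 1000 bp (10000 bp for H3K4me1), or a share of at least 0.25 of the gene body for H3K36me3. Distal H3K27ac regions lay more than 2500 bp from either end of any protein-coding or lncRNA gene. Promoter states were read at the end with more H3K4me3 over the 4 libraries. Where the ends were equal in H3K4me3, the end with more H3K27me3 was taken, and otherwise the start of the gene record. Without strand, the end taken need not be the promoter.

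16 gene lists with 388 entries were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes; all entries matched the gene table, 2 of them by a synonym. For each list and mark, the mean difference (4% minus 20%) in the covered share of the gene window was compared with 10000 random lists of the same size matched on covered share, two-sided, adjusted over 80 tests. The crossed split and the split by set were put through the same test. Members called 4%-only or 20%-only were compared with other genes by Fisher's exact test. Named genes were Nos1, then the 5 oxygen-separating genes per mark and direction ranked by the smallest difference over the 4 pairs of a 4% and a 20% library, and oxygen-separating members of the lists (at most 10 per list and mark for the hypoxia, glycolysis and nitric oxide lists). From every other list at most 3 per mark and direction were taken by the same ranking. The ranking used covered bp within 10000 bp of a gene end, or the share of the body for H3K36me3, and left out genes without an established name. Other genes were chosen after their values were seen: those given for H3K27ac shares, for read density and for regions beside genes.

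For the SICER marks, the deposited counts were summed over the islands of each region that had an island in all 4 libraries and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, log covered length as offset, Benjamini-Hochberg threshold 0.05). Each library thus contributed reads over its own islands, which can differ in extent within a region. A region was assigned to every protein-coding gene it overlapped, so a region can hold several genes. A fit without length offset was therefore added, after the data were seen, for regions of which every library covered at least 0.9. The planned fit had no block. Whether the sets pair the libraries is not stated in the labels. Inputs of a set share a number, but each oxygen level had its own input. All libraries shared a flow cell in set 2 but not in set 1. Deviations from the oxygen means correlated within sets at 0.435 for H3K27me3 and 0.5 for H3K36me3 over regions, which are not independent. The fit with the set as block is therefore printed beside the planned one. Depth as the lists show it was 8479517 to 25048785 reads in islands per SICER library; for the MACS2 marks it is unknown.

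The procedures were tested on simulated data. With 200 of the 10858 H3K36me3 regions changed, the edgeR fit without block recovered 99.0% of the 2-fold and 100% of the 4-fold changes with 5 false calls, and the blocked fit 100% of both with 8. For H3K27me3, over 10177 regions, the false calls were 6 and 5. These simulated counts held no set effect and no change smaller than 2-fold. They therefore do not show how either fit performs with correlated sets or with smaller changes. Of 200 simulated lists of 40 genes without a shift, 5.0% passed p under 0.05. Alternatives were a stricter score threshold, equal peak numbers, at least 50% coverage of a region, a merge gap of 1000 bp, autosomes only, wider gene windows, each library left out, the set as block, no length offset, DESeq2 1.42.0 and a minimum of 10 reads. The stricter score threshold kept the highest-ranked 50% of each library's own list, by score or, for the SICER marks, by island read count. Its cut-off therefore differed between libraries. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and R 4.3.3.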

Results

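The comparison asked how 3 days at 4% oxygen, against 20%, changed the distribution of 5 histone modifications in N1E115 mouse neuroblastoma cells that carry neuronal nitric oxide synthase (NOS1). H3K4me3 marks promoters, H3K27ac active promoters and enhancers, H3K4me1 mainly enhancers, H3K36me3 transcribed gene bodies and H3K27me3 Polycomb-repressed chromatin. Each mark had 2 libraries per oxygen level, 1 in each of 2 sets. H3K4me3 lists held 26489 to 50496 peaks, H3K27ac 60786 to 94286, H3K4me1 99749 to 126503, H3K36me3 17535 to 20804 islands and H3K27me3 22718 to 34471. Reads in islands numbered 13350093 to 25048785 per library for H3K36me3 and 8479517 to 12228541 for H3K27me3; depth is unknown for the other marks. Positions are given in GRCm38.

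At 4% oxygen, H3K27ac covered more of the gene ends of hypoxia response genes, the targets and regulators of the hypoxia-inducible factors. The mean covered share over the 40 list members was 26.7% at 20% oxygen and 34.5% at 4% oxygen, a difference of 7.84 percentage points, with 7.98 in set 1 and 7.70 in set 2. Lists matched on covered share differed by 1.37 points on average (permutation p = 0.0001, the smallest that the permutations can give; adjusted p = 0.0080 over 80 tests). Of the 80 tests of list and mark, 12 had an unadjusted permutation p under 0.05 by oxygen, 7 by the crossed split and 10 by set, and 3, 0 and 1 passed after adjustment; the test by set that passed was H3K27ac at liver and muscle markers, by 5.57 points (adjusted p = 0.0080). The share was higher in both sets for 19 members and lower in both for 2. The largest difference was at Adm, which encodes the peptide adrenomedullin, where H3K27ac covered 15.5% and 12.1% of the windows at 20% oxygen and 95.2% and 76.9% at 4%. Narf went from 15.4% and 6.70% to 36.9% and 33.6%. Pdk1, a kinase that holds back pyruvate dehydrogenase, went from 20.9% and 19.1% to 40.7% and 44.1%. Arnt, the partner subunit of the hypoxia-inducible factors, went from 24.5% and 11.025% to 38.2% and 43.1%. Epo, the erythropoietin gene, went from 13.4% and 11.8% to 26.9% and 50%. No member was 4%-only or 20%-only for H3K27ac, and over all marks no list passed the presence test (Fisher's exact, lowest adjusted p = 0.590).

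Genes of glycolysis and glucose uptake gained H3K27ac as well, with a mean difference of 6.26 points over 26 members against 1.79 in matched lists (permutation p = 0.0014, adjusted p = 0.0373). It was 6.32 points in set 1 against 0.299 in matched lists (permutation p = 0.0007), and 6.21 in set 2 against 3.28, which did not pass there (permutation p = 0.0573). In all, 21 members were higher in both sets and 0 lower in both. Hk2, the inducible hexokinase, went from 30.0% and 23.6% at 20% oxygen to 45.1% and 44.5% at 4%. The glycogen branching enzyme gene Gbe1 went from 23.9% and 32.4% to 46.2% and 43.2%. The glucose transporter gene Slc2a1 went from 19.2% and 36.1% to 43.9% and 41.0%. The call was lost without the 20% library of set 1 (4.41 points, adjusted p = 0.245), the 4% library of set 1 (8.06 points, 0.154) or the 4% library of set 2 (4.47 points, 0.104), and stayed without the 20% library of set 2 (8.11 points, 0.0213).

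**Figure D1:**
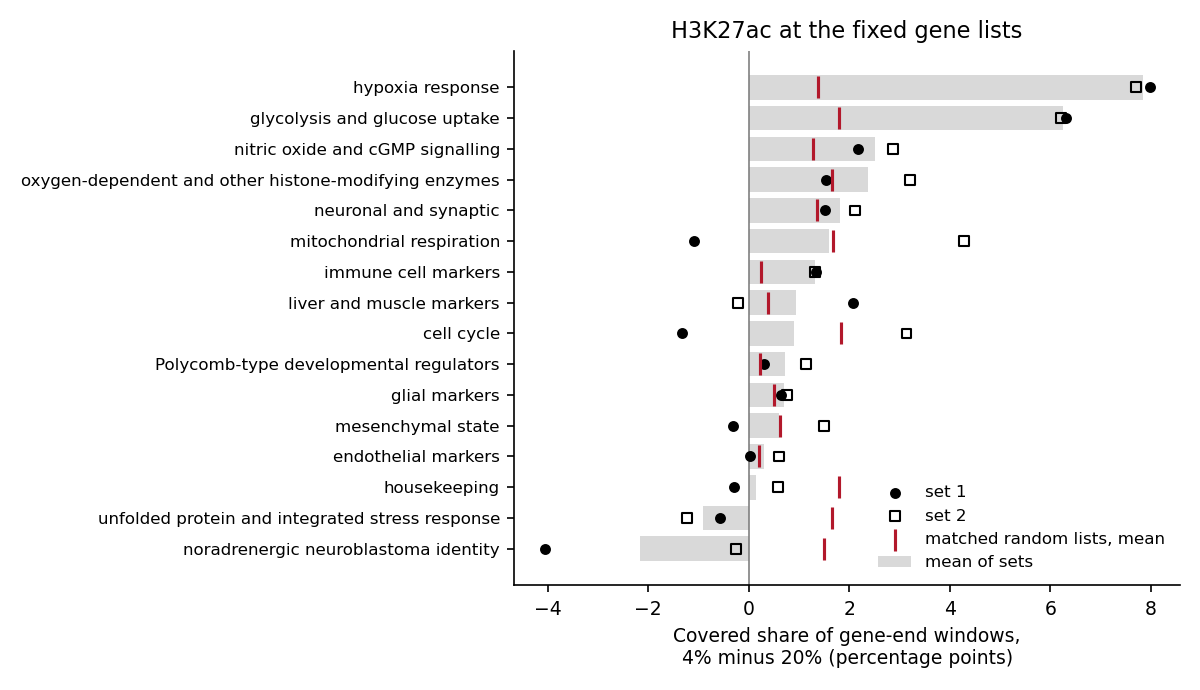
Difference in the H3K27ac covered share of gene-end windows, 4% minus 20% oxygen in percentage points, for the 16 gene lists; bars are the mean of the sets, filled circles set 1, open squares set 2, and red ticks the mean of matched random lists. Hypoxia response genes (7.84) and glycolysis genes (6.26) lie above their ticks.

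Genes of noradrenergic neuroblastoma identity had a mean H3K27ac difference of -2.16 points over 28 members against 1.499 in matched lists, which did not pass the adjusted threshold (permutation p = 0.0058, adjusted p = 0.0928). The set values were -4.06 and -0.25, with 1 member higher and 7 lower in both sets. Nitric oxide and cGMP signalling genes differed by 2.52 points (adjusted p = 0.597). Neuronal and synaptic genes differed by 1.81, histone-modifying enzymes by 2.37, mitochondrial respiration by 1.59, cell cycle by 0.906, mesenchymal state by 0.593, Polycomb-type developmental regulators by 0.721, housekeeping by 0.145 and the unfolded protein response by -0.901 points, and none passed the adjusted threshold. Markers of other cell types stayed near the matched lists: glial markers differed by 0.706 points, immune markers by 1.33, endothelial markers by 0.309 and liver and muscle markers by 0.935 (adjusted p from 0.470 to 0.971).

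In presence calls, 124 genes carried H3K27ac in both 4% libraries and neither 20% library, and 67 the other way round. The crossed split gave 84 genes in all, and the split by set 368, more than the split by oxygen. Under the stricter score threshold the balance turned, with 105 genes 4%-only and 156 genes 20%-only. Urod and Hectd3, neighbours on chromosome 4, were among the 4%-only genes. Covered length around Urod was 1778 ± 709 bp at 20% oxygen and 3888 ± 251 bp at 4% (SD, n = 2 each), and around Hectd3 2258 ± 620 bp and 4582 ± 96.2 bp. Abcc3, Ankrd35 and Cdc42ep2 completed the highest-ranked 4%-only genes, and Kdm2a, a histone demethylase gene, was also 4%-only. Pard3b, Epha8, Med4, Samsn1 and Prss12 led the 20%-only genes. Around Samsn1 H3K27ac covered 828 ± 132 bp at 20% oxygen and 0 bp in both 4% libraries.

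Distal H3K27ac regions, a usual readout of enhancers, were 4%-only in 1820 and 20%-only in 1145 of 65657 cases, against 1592 in the crossed split and 6906 by set. Their directions were associated between sets with an odds ratio of 5.15 (95% interval 4.46 to 5.97, Fisher's exact p = 4.1e-127). H3K4me1 of the same library set overlapped 65.8% and 53.1% of the distal 4%-only regions at 4% oxygen, in sets 1 and 2, and 75.1% and 55.8% at 20% oxygen. Of the 20%-only regions it overlapped 79.9% and 69.4% at 20% oxygen and 58.1% and 58.0% at 4%. For distal regions present in all 4 libraries the overlap was 92.9% and 82.8% at 20% oxygen and 78.5% and 73.8% at 4%. The overlap was thus lower at 4% oxygen for every kind of region.

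H3K36me3 read density, in reads per covered length of each library's own islands, was higher at 4% oxygen over hypoxia response and glycolysis genes once the set was taken into account. The planned edgeR quasi-likelihood fit without block called 0 of 10858 regions at adjusted p under 0.05, with 965 at an unadjusted p under 0.05, and DESeq2 called 2 (650 unadjusted). Leaving out a library gave 23 and 50 calls for the 20% libraries of sets 1 and 2, and 0 and 15 for the 4% libraries. With the set as block, edgeR called 630 regions higher and 529 lower at 4% oxygen. The split by set without block called 16. Without the length offset edgeR called 0 regions without block and 0 with it, with 869 and 1853 at an unadjusted p under 0.05. In the 3677 regions of which every library covered at least 0.9, where all libraries count reads over nearly the same DNA, edgeR without offset called 388 regions higher and 354 lower with the block and 0 without it (370 unadjusted).

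Among regions over hypoxia response genes, 18 of 34 were higher at 4% oxygen and 0 lower in the blocked fit (Fisher's exact test against all regions, adjusted p = 2.2e-12). These regions lay over 16 of the 28 members tested, and the median log2 density ratio was 0.33 against 0.01 for all regions. Without block and adjusted over the list alone, 11 of these regions were higher and 0 lower, and for glycolysis 4 were higher and 1 lower. Of the 14 hypoxia regions with nearly complete coverage in every library, 10 were higher and 0 lower without offset in the blocked edgeR fit. Among them, regions over the mitophagy receptor genes Bnip3l and Bnip3 rose by 0.53 and 0.41 in log2 (adjusted p = 3.0e-08 and 1.3e-06). Those over P4ha2 and P4ha1, which encode collagen prolyl hydroxylase subunits, rose by 0.46 and 0.40 (1.1e-07 and 1.5e-06). Regions are named here for the list member they overlap and can reach into neighbouring genes, so a value need not be that gene's own. The region over Ero1a rose by 0.40 (2.2e-05), and that over Hif1a had a log2 ratio of -0.02 (0.906). In glycolysis and glucose uptake, 12 of 30 regions were higher and 2 lower (adjusted p = 1.2e-06 for the higher ones), and of the 10 with nearly complete coverage 5 were higher and 2 lower. Regions over the hexokinase genes Hk2 and Hk1 rose by 0.50 and 0.41 (3.0e-08 and 6.6e-07). A region over Pfkm fell by 0.39 (5.0e-06), and a region over Pfkfb3 fell by 0.23 (0.0239). No other list passed the adjusted Fisher test for H3K36me3.

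**Figure D2:**
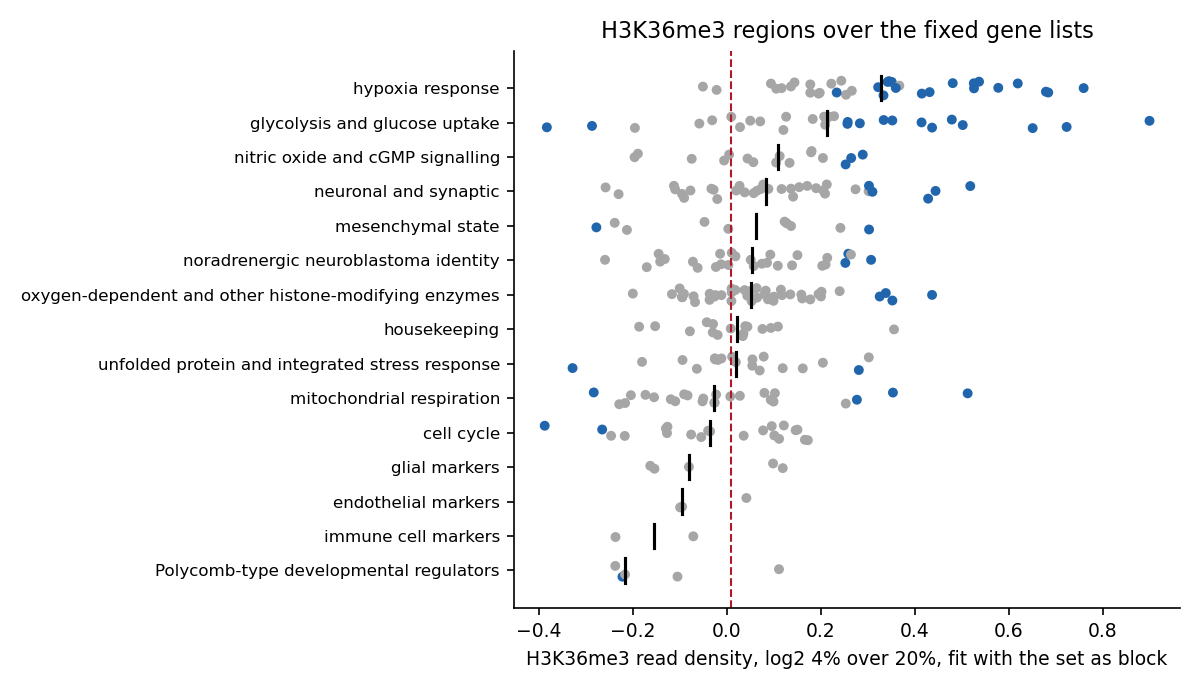
H3K36me3 read density per region, over each library's own islands, for the fixed gene lists, as log2 of 4% over 20% oxygen in the fit with the set as block; each point is a region, blue at adjusted p under 0.05 and grey otherwise, black bars are list medians and the dashed line the median of all regions. The hypoxia response median is 0.33, with 18 of 34 regions higher.

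Nos1 lies on chromosome 5 from 117866839 to 117958840. H3K36me3 covered 97.9% ± 2.95 of the gene at 20% oxygen and 97.5% ± 1.998 at 4% (SD, n = 2 each). The region over it had a log2 density ratio of 0.27 without block (edgeR adjusted p = 0.617) and 0.29 with it (adjusted p = 0.00637). Its islands differed in extent, with at least 0.760 of the region covered in every library, so these densities do not compare the same DNA. No library had H3K27me3 within 50000 bp of Nos1. No library had H3K4me3 within the gene record. The nearest H3K4me3 peaks below it lay between 117840775 and 117843484 in all 4 libraries, next to broad H3K27ac peaks, and on the other side at the start of the neighbouring gene record of Fbxo21. Within the gene and 50000 bp on either side H3K27ac covered 8176 and 12082 bp at 20% oxygen and 9237 and 12425 bp at 4%. Ddah1 passed the presence rule for H3K36me3 at 4% oxygen alone, with 32.5% and 33.0% of its body covered against 3.89% and 22.3% at 20%, the latter close to the threshold. The region tested over its end had a log2 density ratio of -0.01 (blocked edgeR adjusted p = 0.986), with the same limit, as the lowest covered share was 0.727.

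In covered share, H3K36me3 at hypoxia response genes differed by 4.17 points against -1.62 in matched lists (permutation p = 0.0004, adjusted p = 0.0160), but the sets gave 9.47 and -1.12, and the crossed split gave 5.30 points (permutation p = 0.0138). The call was lost with equal peak numbers (adjusted p = 0.054) and without the 20% library of set 1 (0.243) or the 4% library of set 1 (0.523). By the presence rule 30 genes were 4%-only and 183 were 20%-only for H3K36me3. The split by set gave 239 genes and the crossed split 108, with 96 one way and 12 the other. The 4%-only count thus lay below the larger direction of the crossed split. Ctla2a, Eef1akmt3, Gpr3, Cdkn2d and Mrgprf led the 4%-only genes. Ctla2a had 82.8% ± 11.4 of its body covered at 4% oxygen and 0% at 20%. Zrsr1, Emid1, Gpd1, Pla2g4b and Msmp led the 20%-only genes. Emid1 had 92.1% ± 0.921 covered at 20% oxygen and 0% at 4%. Insm1, of the noradrenergic list, and Cldn5, an endothelial marker, were also 20%-only.

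H3K4me1 covered less of the genome at 4% oxygen in both sets. It spanned 93.8 ± 17.1 Mb at 20% oxygen and 62.4 ± 1.96 Mb at 4% (SD, n = 2 each), a ratio of 0.576 in set 1 and 0.780 in set 2 (exact permutation p = 0.333, the smallest possible). By region, 9560 were 20%-only and 1241 were 4%-only. By gene, 1389 were 20%-only and 6 were 4%-only, against 135 in the crossed split (13 one way and 122 the other) and 394 by set. The 4%-only count thus did not exceed either direction of the crossed split. Of the 20%-only regions 39.4% lay near a gene end, compared with 12.2% of the 4%-only regions and 25.7% of all H3K4me1 regions. Ubl5, Fbxl12, Cutal and Psmd5 were among the highest-ranked 20%-only genes, and around Fbxl12 the mark covered 2414 ± 77.1 bp at 20% oxygen and 0 bp at 4%. List members that were 20%-only included Arnt and Dynll1, the cell cycle genes Mcm7, Ccna2 and Plk1, the mitochondrial genes Tfam, Uqcrc2 and Ndufv1, and Maml2, Sox9, Foxa1, Hdac2, Aldh1l1 and Lyz2. Car9, the hypoxia-inducible carbonic anhydrase gene, was 4%-only, with 250 ± 23.3 bp covered at 4% oxygen and 0 bp at 20%. Spg21, Mtfmt, Timp4 and Zfp971 were 4%-only too, with 201 to 205 bp in set 2 at 4% oxygen for Spg21, Mtfmt and Zfp971. No list passed the adjusted threshold for H3K4me1.

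**Figure D3:**
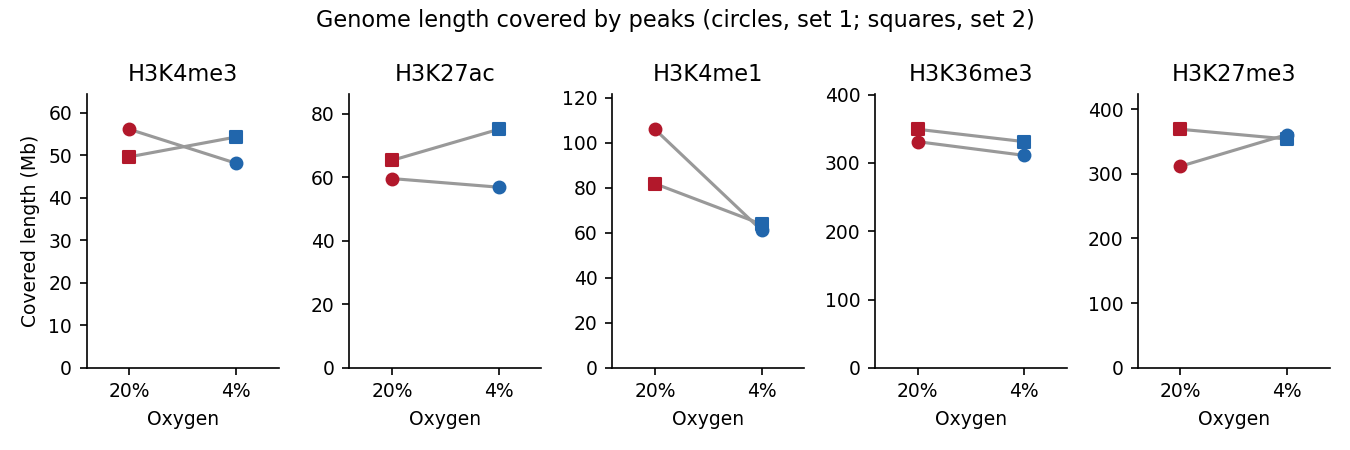
Genome length covered by the peaks of each library in Mb, for the 5 marks at 20% (red) and 4% (blue) oxygen; circles are set 1, squares set 2, and grey lines join the libraries of a set. H3K4me1 covered 105.9 and 81.8 Mb at 20% oxygen and 61.0 and 63.8 Mb at 4%.

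For H3K27me3, by the presence rule 192 genes were 4%-only and 62 were 20%-only. Over all regions 500 were 4%-only and 761 were 20%-only, but this balance turned with equal peak numbers (501 and 428) and with at least 50% of a region covered (904 and 653). The crossed split gave 81 genes one way and 19 the other, and the split by set 310 in all, more than the split by oxygen. In set 1 the mark was at 3595 genes at 20% oxygen and 4351 at 4%, and in set 2 at 3747 and 3844. Vip, which encodes the neuropeptide VIP, had 5617 ± 849 bp of H3K27me3 around it at 20% oxygen and 22325 ± 7495 bp at 4%. Mogat1 had 1570 ± 890 and 16400 ± 1697 bp, C5ar1 4500 ± 424 and 16700 ± 424 bp, and the neighbours Aldh3b2 and Aldh3b3 had 0 bp at 20% oxygen and 12836 ± 2597 and 15200 ± 5940 bp at 4%. Dbx1, Ccl7, Serpina16, Smok2b and Adamtsl1 led the 20%-only genes, with 14302 ± 849 bp at 20% and 1800 ± 2546 bp at 4% for the homeobox gene Dbx1. Covered length as such was 340.1 ± 40.4 Mb and 357.2 ± 4.92 Mb, with 311.6 and 368.7 Mb at 20% oxygen and 360.6 and 353.7 Mb at 4% in sets 1 and 2. In read density edgeR called 0 of 10177 regions without block, with 964 at an unadjusted p under 0.05 and 0 by DESeq2, and 790 higher and 322 lower with the set as block. Without block, leaving out the 4% library of set 1 gave 38 calls and that of set 2 gave 136, and leaving out either 20% library gave 0 (735 and 607 unadjusted). Without the length offset edgeR called 0 regions, with 686 at an unadjusted p under 0.05 without block and 2394 with it. In the 1129 regions with nearly complete coverage it called 254 higher and 224 lower with the block and 0 without (173 unadjusted).

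H3K4me3 was 4%-only at 18 genes and 20%-only at 23. The split by set gave 138 genes and the crossed split 33, with 3 one way and 30 the other. Neither oxygen count thus exceeded the larger direction of the crossed split. Under the stricter score threshold 9 genes were 4%-only and 5 were 20%-only. Apol9a, Chrm1, H2bc7, H4c3 and Slc23a4 led the 4%-only genes, and the histone gene H4c3 had 80 ± 113 bp covered at 20% oxygen and 416 ± 175 bp at 4%. Gbp5, Efcab6, Tspo2, Cacnb4 and Tmem35a led the 20%-only genes, with 2929 ± 5.66 and 1497 ± 225 bp at Gbp5; the difference at Tmem35a changed sign under the stricter threshold. Cd68 was 4%-only near its ends, while the wider window had 4530 ± 196 bp at 20% oxygen and 4394 ± 17.7 bp at 4%. No list passed the adjusted threshold (lowest adjusted p = 0.470).

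At promoters, 44.4% and 45.9% of genes had H3K4me3 with H3K27ac at 20% oxygen and 44.1% and 47.1% at 4%. In both sets 89 genes, Adm among them, moved from H3K4me3 alone at 20% oxygen to H3K4me3 with H3K27ac at 4%. The opposite move was made by 49 genes. The crossed split gave 21 and 44 such moves, and the split by set, from set 1 to set 2, 209 and 28. From neither H3K4me3 nor H3K27me3, 83 genes moved to H3K27me3 alone and 61 moved back. For these moves the crossed split gave 64 and 15, and the split by set 104 and 89, more than oxygen. They can have been read at an end chosen by H3K27me3, which need not be the promoter. In all 347 genes changed state with oxygen in both sets, 592 changed between sets at both oxygen levels, and 179 changed in the crossed split.

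Directions of change were associated between sets for every mark. The odds ratio was 5.38 for H3K27me3 (95% interval 4.36 to 6.66), 5.12 for H3K27ac (4.52 to 5.80), 3.40 for H3K4me1 (3.10 to 3.73), 3.07 for H3K4me3 (2.20 to 4.33) and 1.97 for H3K36me3 (1.52 to 2.54), with Fisher's exact adjusted p of at most 8.8e-08. Association was not identity: of H3K36me3 regions 4%-only in set 1, 47.1% were 4%-only in set 2 against 31.1% of those 20%-only in set 1, and for H3K4me3 the shares were 76.9% and 52.0%. Regions lie next to each other and are not independent; by chromosome the odds ratio was above 1 in 18 to 20 of 20 chromosomes (exact sign test p of at most 0.0004). The set still separated more regions than oxygen, with 9184 against 4054 for H3K27ac, 12016 against 10801 for H3K4me1, 3352 against 538 for H3K4me3, 1105 against 709 for H3K36me3 and 2790 against 1261 for H3K27me3. On average, libraries of the same set shared more covered length than libraries of the same oxygen level, for example with a mean Jaccard index of 0.637 against 0.587 for H3K27ac. The pairs of 20% libraries of H3K4me1 (0.482) and H3K36me3 (0.828) were above the same-set pairs of their mark.

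**Figure D4:**
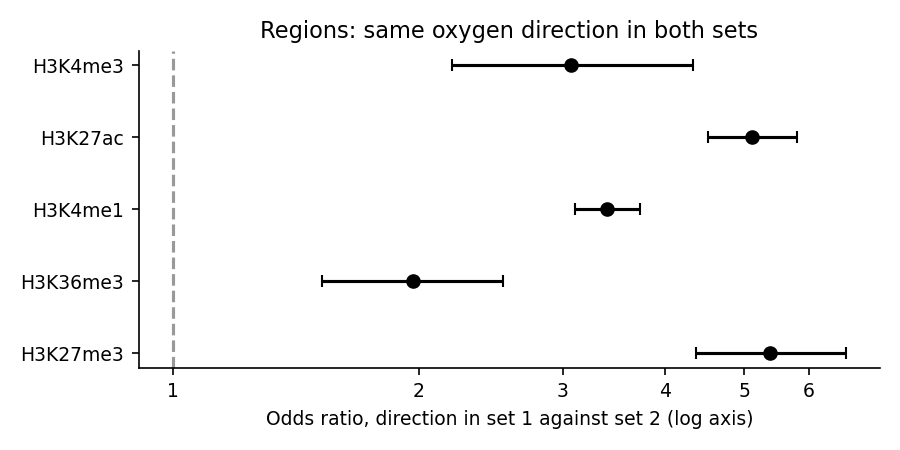
Odds ratio, on a log axis, between the oxygen direction in set 1 and that in set 2, over regions decided in both sets, per mark; points are estimates, bars 95% intervals, and the dashed line marks 1. All 5 intervals lie above 1, from 1.97 for H3K36me3 to 5.38 for H3K27me3.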

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

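The alternative with the whole gene and 10000 bp on either side, the block without length offset, and the fits of nearly completely covered regions were chosen after the data were seen. Direction odds ratios between sets kept their direction and stayed past the threshold under each alternative run, as did H3K27ac at hypoxia response genes, also without each library. The choice of any annotated transcript start was not run, and a minimum of 10 reads removed no region. The stricter threshold left 48 oxygen-separating H3K4me3 regions, 2096 H3K27ac, 6246 H3K4me1, 332 H3K36me3, 692 H3K27me3 and 1340 distal H3K27ac regions, and 14 H3K4me3 genes. Its peak lists were shorter by construction, but its counts of separating regions and genes need not be. Equal peak numbers left 298 H3K4me3 regions and 20 genes. A merge gap of 1000 bp gave 1570 H3K27ac and 5184 H3K4me1 regions. The split of H3K27me3 regions moved from 39.7% at 4%-only to 53.9% with equal peak numbers and 58.1% with at least 50% coverage, and that of H3K27ac genes from 64.9% to 40.2% under the stricter threshold; the cause was not tested. The H3K36me3 covered length ratio (log2) was -0.08, and -0.0687 under the stricter threshold. With the set as block (replicate block), covered length ratios moved by less than their spread (-0.58 for H3K4me1 against -0.59), while read density gave 1112 H3K27me3 and 1159 H3K36me3 regions against 0 without, and the block changed no other call; DESeq2 gave 2 for H3K36me3. In regions of which every library covered at least 0.9 the block without offset gave 478 H3K27me3 and 742 H3K36me3 regions. H3K36me3 at hypoxia genes fell short of the threshold with equal peak numbers (4.80 points over matched lists), and H3K27ac at noradrenergic genes passed it over the whole gene with flanks (-3.45 points, adjusted p = 0.004). The cause was not tested. Over all alternatives the adjusted p ranged from 0.002 to 0.523 for the former, from 0.004 to 0.320 for the latter and from 0.002 to 0.245 for H3K27ac at glycolysis genes.

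Leaving out a library loosens the rule for regions and genes, so counts rose: H3K4me3 regions 1623 to 6434 and genes 120 to 170, H3K27ac 10444 to 23717 and 498 to 558, H3K4me1 24889 to 45187 and 1738 to 2771, H3K36me3 1759 to 2693 and 389 to 744, H3K27me3 3508 to 4828 and 538 to 848. Covered length (log2) ranged from -0.14 to 0.27 for H3K27ac and from -0.13 to -0.0388 for H3K36me3. Differences over matched lists ranged from 3.13 to 5.82 points for H3K27ac at glycolysis genes and from 3.58 to 8.02 for H3K36me3 at hypoxia genes. Read density calls ranged from 0 to 136 for H3K27me3 and 0 to 50 for H3K36me3, the lone library being assumed to vary like the others. The H3K4me3 difference changed sign at Tmem35a, to 12.5 bp under the stricter threshold, and at Cd68, which ranged from -274.5 to 2.5 bp with a library left out. The cause was not tested. Depth is unknown for the MACS2 marks, so missing peaks there do not show absence.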

Other observations

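The tests on regions beside genes, chromosomes, peak yield at hypoxia genes and H3K27ac and H3K4me1 flow cells were chosen only after the result was seen. So were those on noradrenergic genes in set 2 and on the crossed split. Beside a gene here means over the gene itself or within 50000 bp of either end. Beside noradrenergic identity genes 6 H3K27ac regions were 4%-only and 24 were 20%-only, against 2527 and 1497 elsewhere (Fisher's exact p = 3.0e-06, adjusted p = 0.000239 over 80 tests). The 20%-only regions included 6 beside Alk and 2 each beside Hand2, Gata2, Tfap2b and Insm1, transcription factor genes of sympathetic neurons, while Cyb561 had 3 4%-only regions. Beside hypoxia response genes 33 regions were 4%-only and 4 were 20%-only (adjusted p = 0.0187), with 3 4%-only regions each beside Egln3, Ankrd37 and Narf, and 2 of the 20%-only regions beside Narf. Beside glycolysis genes the numbers were 16 and 2 (adjusted p = 0.406), with 5 beside Slc2a1. Regions near each other are not independent, so these p-values are too small. The windows also contain the gene ends at which covered shares were compared, so the counts are not separate evidence from those shares.

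A candidate explanation for the noradrenergic pattern is the flow cell difference of set 1. In set 2, where both H3K27ac libraries shared a flow cell and lane, the odds of being 4%-only were still lower beside the list (odds ratio 0.345, 96 against 153 regions, exact p = 1.2e-16). Set 2 had also entered the pattern itself, so this was not an independent test. Oxygen, antibody efficiency and other differences between the libraries stay open.

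Hypoxia response genes gained H3K27ac coverage and H3K36me3 read density. For H3K27ac coverage, unequal peak number is argued against. With equal peak numbers the difference was 8.04 points against 1.35 in matched lists (permutation p = 0.0001, the smallest possible). Depth and covered length were not made equal, so other differences in yield stay open. H3K36me3 read density was not tested in this way. The flow cell was the same for both libraries of set 2, where the H3K27ac difference was 7.70 points. There 31 of 34 H3K36me3 regions lay above the median of all regions (exact sign test p = 7.7e-07). Set 2 had also entered both patterns, so this was not an independent test. Without the length offset 32 of the 34 regions stayed above the median (exact sign test p = 6.9e-08). That concerns the offset alone, since unequal island extent enters these counts. Of the 14 that every library covered almost whole, 13 lay above the median of such regions (exact sign test p = 0.0018). For these 14, that argues against islands of unequal extent. Regions over the same gene are not independent, so these p-values are too small. The crossed split with block called 0 regions, but with 1 residual degree of freedom it restates the 1159 calls by oxygen, so a structure of the sets stays open. A response to oxygen is a candidate source; depth and antibody efficiency were not tested separately.

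The smaller H3K4me1 length at 4% oxygen could come from a lower peak yield alone. The prediction was that lost regions lie near gene ends as often as equally wide regions found in 2 libraries by the other splits. They did so more often (39.4% against 19.3%, Mantel-Haenszel odds ratio 2.61, 95% interval 2.46 to 2.76). This cannot decide, since a lower yield need not remove regions evenly with respect to gene ends. Flow cells were shared within both sets, and the log2 ratio was -0.58 ± 0.31 (SD, n = 2 sets). Lanes differed within both sets, and fragment length or antibody efficiency was not tested, so these and a lower yield stay open beside oxygen.

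The oxygen direction of H3K27me3 regions differed between chromosomes, whose neighbouring regions are not independent. On X 26 regions were 4%-only and 3 were 20%-only, on chromosome 15 the numbers were 41 and 13, and on chromosome 2 they were 43 and 17. Chromosome 4 had 24 and 95, chromosome 18 had 11 and 68 and chromosome 14 had 8 and 50 (Fisher's exact adjusted p of at most 0.000247 over 100 tests of chromosome and mark). The share of 4%-only among decided regions in sets 1 and 2 lay on opposite sides of 50% for X (93.8% and 37.6%) and chromosome 15 (43.1% and 86.3%). It lay on the same side for chromosomes 2 (54.0% and 78.5%), 4 (33.3% and 22.8%), 14 (37.8% and 22.1%) and 18 (22.5% and 23.1%).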
